A study of Rattus norvegicus with 6 samples.

How the data were processed

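Total RNA from the livers of Sprague-Dawley rats was measured on 6 single-colour Agilent arrays, 1 per liver sample, after labelling of 0.5 µg of RNA with the dye Cy3. Per the labels, 2 samples came from rats without infection, 2 from rats infected with the liver fluke Clonorchis sinensis for 2 weeks, and 2 from rats infected for 4 weeks. The labels do not say that the replicates of a group are separate animals, so p-values of genes measure only the spread between these samples, which may be technical. Each array carried 44254 spots, of which 42877 were not controls, for 30367 probes.

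The authors deposited the scanner output of each array, and per the file headers it was made with Agilent Feature Extraction version 11.0.1.1 under its single-colour protocol. Per the file headers the processed signal is an intensity on a linear scale, with background subtracted and spatial trends removed within each array, and it is not scaled between arrays. The deposited files also hold other values per spot, such as flags for a signal well above background, for saturation and for outlier spots. A table of the authors' processed values was deposited too; its scale is not given in the sources used here. Set against the scanner signals, its values for all 27078 targets matched, within 0.01, the log2 of the mean log2 processed signal over the spots of a target, so the authors had taken log2 a second time without centring. The column medians were 2.76 and 2.80 without infection, 2.94 and 2.90 at 2 weeks, and 2.99 and 2.90 at 4 weeks. The files give no direction for these values, as each column is 1 array.

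From the scanner files, control spots and outlier spots were left out, the log2 processed signals of the spots of a probe were averaged, and the 75th percentile of each array was subtracted. A probe was kept if it was well above background on at least 2 of the 6 arrays, which left 21021 probes, and 19 probes missing on an array were dropped. Target accessions were matched without versions to a RefSeq gene table of the assembly GRCr8, which named 17328 probes (57.1%). The probe with the highest mean over the arrays stood for each gene name, and an unnamed target stood for itself, which gave 18822 genes tested, 10845 of them with a gene symbol. The grid of the array design refers to the older genome build rn4, so no coordinates are given.

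Differences were tested in R 4.3.3 with limma 3.58.1, by lmFit and eBayes over all 6 arrays with 3 residual degrees of freedom, with 2-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Beside it stand a descriptive count of genes at least 2-fold apart at an unadjusted p under 0.01, and the count from a fit of the 2 groups compared alone, whose spread does not include the third group. Errors of log2 differences are standard errors of the fit over all 6 arrays, also where a p-value or a call of another fit stands beside them. Lists of genes, 40 in all, were fixed for cell types and pathways of liver and for tissues carried along with it. They were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 40 lists, and again with an estimated correlation and with fry. At the preset correlation camera's p-values rest on the spread across genes, taken as almost independent, rather than on the spread between arrays. The estimated correlation was 0.916 for cell cycle, 0.939 for urea cycle and 0.645 for bile duct genes, but 0.009 for T cell markers. Where it is far above 0.01, the p-values at the preset correlation are likely too small. Fry asks whether the genes of a list move, on balance, 1 way, and does not compare the list with other genes. With an estimated correlation camera has only the 3 residual degrees of freedom, and its power was not measured. A list not called with an estimated correlation is therefore not shown to be unchanged. Where a group had no array well above background for a gene, the difference is given as a bound: the mean of the brighter group was set against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal well above background. The fits were tested on simulated data with the uninfected means of the 18822 genes. The spread of each gene was drawn at random from the distribution that limma fitted to the arrays, and was the same in every group. With 50 genes changed by 4 on the log2 scale, the fit over all 6 arrays called 36 of the 50 for 2 weeks against no infection. It called 32 for 4 weeks against no infection and 33 for 4 weeks against 2 weeks. With a true log2 change of 2 the same fit called 2, 2 and 3 of 50, and with a change of 1 it called 0 of 50 in each comparison. In the fit of the 2 groups alone, changes of 4 were called in 43, 6 and 1 of 50 genes. The real 4-week arrays differed from each other more than the other pairs did, so these rates need not hold for the real arrays.

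The arrays came from 2 slides, each scanned as 1 batch. Slide 1 held 2-week replicate 1 and both 4-week arrays, and slide 2 held both uninfected arrays and 2-week replicate 2. With the slide as a block, the 2-week difference equals 2-week replicate 2 minus the uninfected mean, within slide 2, and the difference between 4 and 2 weeks equals the 4-week mean minus 2-week replicate 1, within slide 1. The 4-week difference from no infection is then the sum of both, since no slide held both groups. Values with the slide as a block are given for the chief genes and lists, and wherever the block ends the call of a list.

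The design, the tests, the lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The rule names, per comparison, the 10 genes with a symbol that rose most and the 10 that fell most among called genes whose groups do not overlap. Where fewer pass, it adds the genes with the smallest p among those at least 2-fold apart, described as not passing. For each list it adds the 4 measured members with the smallest p and up to 6 called members. The text names part of the genes that the rule gives, picked after their values were seen. No named gene had probes called in opposite directions, but with every probe on its own 0 probes were called in each comparison. This therefore does not show that the probes of a gene agree. The alternatives were other scalings (quantile, median centring, a percentile over probes above background on every array), other filters on dim probes, other ways to combine probes, the authors' values, the fit of the 2 groups alone, an intensity trend with a robust prior, array weights, the replicate number or the slide as a block, a floor, stricter thresholds, and leaving out each array. A background correction by normexp with an offset of 50 was planned on mean spot signals, which the files do not hold, and was run on median spot signals instead, a choice made after the data were seen. Precision is limited by the number of arrays and, for dim genes, by the signal over background; the share of spots well above background ran from 67.6% to 76.1%, and no spot was saturated.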

Results

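The dataset records gene expression in the liver of rats that were free of Clonorchis sinensis, a fluke that lives in the bile ducts, or had carried it for 2 or 4 weeks. There were 2 arrays in each of the 3 groups, and 18822 genes were tested. The 75th percentile of the processed signal was 1562 and 1649 in the uninfected arrays, 2431 and 1981 at 2 weeks, and 2900 and 1949 at 4 weeks. Between 67.6% and 76.1% of the spots were well above background.

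The arrays of the uninfected pair (r = 0.986 across genes) and of the 2-week pair (r = 0.976) resembled each other more than those of the 4-week pair (r = 0.882). Genes are not independent replicates in these correlations. The 4-week replicate 1 lay closest to 2-week replicate 1 (r = 0.979), and 4-week replicate 2 lay closest to uninfected replicate 2 (r = 0.979). The first principal component held 76.2% of the variance and parted both uninfected arrays and 4-week replicate 2 from the other 3 arrays. The standard deviation of the difference between replicates was 0.55 without infection, 0.63 at 2 weeks and 1.41 at 4 weeks on the log2 scale, so the 4-week pair sets most of the spread in a fit over all 6 arrays.

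**Figure D1:**
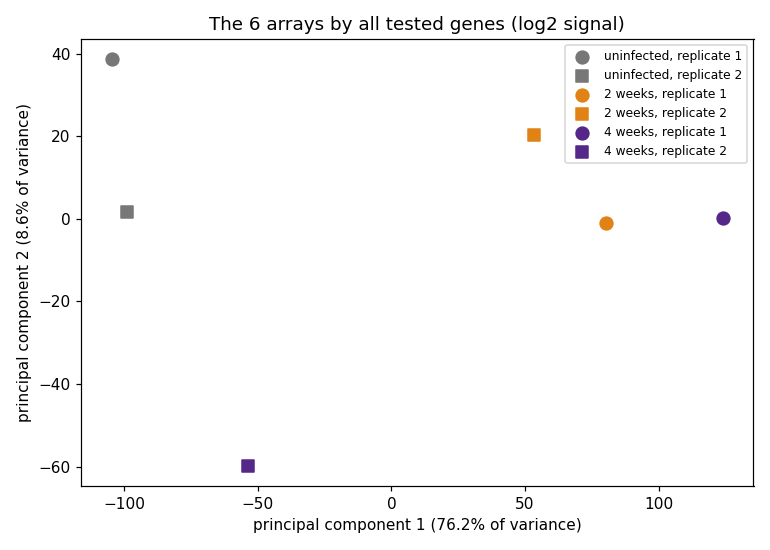
Position of each of the 6 arrays on the first and second principal components of the log2 signal of all tested genes; points are arrays, colours are groups and shapes are replicates. The first component holds 76.2% of the variance, and 4-week replicate 2 sits on the side of the uninfected arrays.

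The first comparison asked how the liver differed at 2 weeks of infection from the uninfected liver. At 2 weeks the liver showed bile duct, mucin, extracellular matrix, myofibroblast, cell cycle and mast cell genes at higher levels than the uninfected liver, and hepatocyte genes of nitrogen, fatty acid, bile acid and drug metabolism at lower levels. These are calls of camera at the preset correlation, and none of the 40 lists was called with an estimated correlation (smallest adjusted p = 0.462 with an estimated correlation) or with fry. The eosinophil chemoattractant Ccl11 rose: it was not well above background in either uninfected array, and was at least 703-fold higher at 2 weeks (log2 difference 10.15 ± 0.42, SE, n = 2 per group, adjusted p = 0.0487; 9.89 with the slide as a block). The median log2 difference was 4.09 over 20 bile duct genes (4.23 and 3.85 in the 2 arrays) and -1.01 over 47 hepatocyte genes (-1.08 and -0.93).

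Ccl11 was the only gene that passed in limma's fit over all 6 arrays, with 2437 genes at an unadjusted p under 0.05 and 527 genes at least 2-fold apart at an unadjusted p under 0.01, 482 of them higher and 45 lower. Under limma 0 genes passed with the slide as a block, with 694 at an unadjusted p under 0.05. In the fit of the 2 groups alone, which leaves out the spread of the 4-week pair, 4160 genes passed, of which 2306 rose and 1854 fell. The median standard error was 0.35 in the first fit and 0.20 in the second. The groups did not overlap for 71.7% of genes, where chance gives 33.3%. The median over all genes was -0.15. It was -0.41 with median centring, -0.19 with quantile normalization and -0.48 with normexp, so the differences here are relative to such shifts. Of the genes 2-fold apart, 91.5% were higher in the main scaling, 73.1% after quantile normalization and 56.7% with median centring. Below, a gene or list member is said to have risen or fallen in the fit of the 2 groups alone where it passed there at an adjusted p under 0.05; apart from Ccl11, none of these passed in the fit over all 6 arrays.

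Genes of bile duct epithelium and its secretions stood far above the uninfected level in both 2-week arrays. Of 20 measured bile duct markers 14 rose and 6 did not pass in the fit of the 2 groups alone. Among the risen was the duct keratin Krt7, at a log2 difference of 8.36 ± 2.34 (error of the fit over all 6 arrays). It passed at an adjusted p = 0.00535 in the fit of the 2 groups alone. Others were the tight junction protein Cldn4 (8.37 ± 2.31) and the chloride channel Cftr (5.82 ± 1.58). The secretin receptor Sctr was not well above background without infection and was at least 2.17-fold higher. Of 10 mucin and secretory genes 8 rose, 1 fell and 1 did not pass. The trefoil peptide Tff1 was at least 2930-fold higher, the mucus protein Fcgbp at least 93.5-fold, the intestinal lectin Itln1 at least 7.70-fold and the antibacterial lectin Reg3g at least 5.42-fold. With normexp Sctr and Reg3g turned to -1.10 and -0.06. Of 14 liver progenitor and oncofetal genes 9 rose and 5 did not pass, among them the imprinted transcript H19 (2.57 ± 0.48) and the glypican Gpc3 (2.35 ± 0.54). Adjusted over the list alone in the fit over all 6 arrays, 1 bile duct, 4 mucin and 7 progenitor genes rose. Over all genes 0 of them passed. The list medians were 4.09, 4.67 and 1.59, or 3.75, 4.58 and 1.30 with members at their bound, and 3.85, 5.39 and 1.39 with the slide as a block. With normexp they were 2.64, 2.44 and 0.12. Camera called all 3 lists upward (adjusted p = 2.32e-08, 5.36e-06 and 1.39e-05). None was called with an estimated correlation (adjusted p = 0.462 with an estimated correlation for each).

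Extracellular matrix, myofibroblast, matrix protease and cell cycle genes were higher as well. Of the collagen and extracellular matrix genes 17 of 31 rose, 1 fell and 13 did not pass in the fit of the 2 groups alone. Of the stellate cell and myofibroblast genes 12 of 18 rose, 2 fell and 4 did not pass. The microfibril protein Mfap5 was higher by 2.97 ± 0.33, the proteoglycans Lum and Dcn by 3.50 ± 0.58 and 2.71 ± 0.45, and the matrix protein Postn at least 49.9-fold. The smooth muscle actins Actg2 and Acta2 were higher by 4.01 ± 0.28 and 1.86 ± 0.23, the intermediate filament Des by 3.52 ± 0.49, and the calponin Cnn1 at least 4.11-fold. Of 20 matrix proteases and inhibitors 11 rose and 9 did not pass. Among them stood Plat, the tissue plasminogen activator, at 2.87 ± 0.64 and the gelatinase Mmp2 at 2.46 ± 0.73. Of 39 cell cycle genes 31 rose and 8 did not pass. Examples were the spindle protein Tpx2 (1.75 ± 0.49) and the kinetochore protein Cenpf (at least 4.73-fold). Cnn1, Tpx2 and Cenpf turned to -0.45, -0.59 and -0.26 with normexp. Adjusted over the list alone in the fit over all 6 arrays, 15 matrix genes, 10 myofibroblast genes, 0 proteases and 0 cell cycle genes rose, against 0 over all genes. The medians were 1.60, 1.85, 1.64 and 2.45, or 1.31, 1.79, 1.36 and 2.15 with the slide as a block. Camera called all 4 lists upward (adjusted p = 2.78e-11, 9.40e-08, 4.69e-05 and 7.51e-14). With an estimated correlation none was called (adjusted p = 0.462 with an estimated correlation for the first 3 lists and 0.540 for cell cycle).

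Immune genes differed by cell type. Of 16 mast cell markers 12 rose, 1 fell and 3 did not pass in the fit of the 2 groups alone. They included the IgE receptor chain Fcer1a (2.96 ± 0.44), the protease Mcpt8 (2.15 ± 0.35) and the serotonin enzyme Tph1 (at least 4.13-fold). Of 6 eosinophil markers 3 rose and 3 did not pass. The risen ones were the ribonucleases Rnase2 (at least 12.4-fold) and Rnase3 (at least 3.79-fold) and the Ccl11 receptor Ccr3 (at least 3.96-fold). Of 21 type 2 cytokine and response genes 4 rose, 1 fell and 16 did not pass, with the resistin-like Retnlb at least 42.6-fold higher. Il1rl1, the receptor of interleukin 33, was at least 3.57-fold higher and did not pass (adjusted p = 0.0587 in the fit of the 2 groups alone). Of 13 B and plasma cell markers 5 rose and 8 did not pass. Examples were the plasma cell protein Mzb1 (3.70 ± 0.53) and the coactivator Pou2af1 (3.08 ± 0.64). Adjusted over the list alone in the fit over all 6 arrays, 9 mast cell, 3 eosinophil, 2 type 2 and 4 B cell genes rose, against 1 gene, Ccl11, over all genes. The medians were 2.15, 2.14, 0.75 and 0.24, and 2.01, 1.77, 0.35 and 0.43 with the slide as a block. With members at their bound the eosinophil median was 1.15. Camera called the 4 lists upward (adjusted p = 5.19e-09, 0.00486, 0.0183 and 0.0440), none with an estimated correlation (adjusted p = 0.462 with an estimated correlation for each). The medians of the eosinophil, type 2 and B cell lists turned to -0.48, -0.71 and -0.71 when the background was corrected by normexp, with the 3 calls lost, and the mast cell median was 0.08. Genes that turned with it were Tph1 (-0.32), Rnase3 (-0.42), Ccr3 (-0.35) and Il1rl1 (-0.71). The median over all genes was -0.48 with normexp, so such values are relative to that shift. Camera called the list of natural killer and cytotoxicity genes downward, with a median of -0.42 over 16 genes (adjusted p = 0.0220). The call was lost with an estimated correlation (adjusted p = 0.697 with an estimated correlation) and with the slide as a block (adjusted p = 0.105, at a median of -0.42). Of its genes 2 fell and 14 did not pass in the fit of the 2 groups alone, and 0 passed adjusted over the list alone.

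Transcripts of 8 lists of hepatocyte genes were lower at the preset correlation. Of 47 hepatocyte identity and secreted protein genes 27 fell, 1 rose and 19 did not pass in the fit of the 2 groups alone, with the coagulation factor F7 at -1.93 ± 0.66 and the regulator Foxa2 at -1.08 ± 0.28. Of 38 genes of the urea cycle and amino acid breakdown 25 fell and 13 did not pass, among them Agxt (-1.85 ± 0.76) and Hgd (-1.72 ± 0.73). Of 42 fatty acid oxidation genes 17 fell, 2 rose and 23 did not pass, with the dehydrogenase Acadl at -0.99 ± 0.33. Of 27 cytochrome P450 genes 13 fell, 1 rose and 13 did not pass. Of 21 bile acid synthesis genes 14 fell and 7 did not pass, with the sterol 12-alpha-hydroxylase Cyp8b1 at -2.02 ± 0.93. The medians were -1.01, -1.23, -0.96, -1.14 and -1.03, and -0.93, -1.12, -0.84, -1.04 and -0.96 with the slide as a block. Camera called the 5 lists downward (adjusted p = 1.82e-05, 9.56e-05, 2.20e-04, 0.0122 and 0.0154). None of the 5 was called with an estimated correlation (adjusted p = 0.697 with an estimated correlation for each). Camera also called downward the acute phase list, with a median of -0.74 (adjusted p = 0.0204, and adjusted p = 0.697 with an estimated correlation). In it 11 of 35 genes fell, 3 rose and 21 did not pass in the fit of the 2 groups alone, with the iron hormone Hamp at -1.89 ± 0.55 and the siderophore-binding Lcn2 at 2.87 ± 0.68. The list of cholesterol synthesis had a median of -0.66 (adjusted p = 0.0251; 4 of 26 fell and 22 did not pass) and that of sex-dependent liver genes -1.14 (adjusted p = 0.0473; 3 of 11 fell and 8 did not pass). These 2 calls were lost too (adjusted p = 0.697 with an estimated correlation for each). In the fit over all 6 arrays 0 genes of the 8 lists passed adjusted over the list alone. With normexp the medians of the acute phase and cholesterol lists turned to 0.08 and 0.16. Those of the hepatocyte, urea cycle and fatty acid oxidation lists stayed below 0 at -0.14, -0.29 and -0.10, though camera, which compares a list with all other genes, read these 3 upward. None of the 8 lists was called downward with normexp.

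Markers of other tissues moved in the same samples. The pancreatic acinar list had a median of 5.08 (camera, adjusted p = 0.00117; adjusted p = 0.697 with an estimated correlation), or 4.74 with members at their bound, but its median was -0.42 in 2-week replicate 1 and 9.66 in replicate 2. Of its 14 measured genes 1 rose and 13 did not pass in the fit of the 2 groups alone, and 0 passed adjusted over the list alone. The ribonuclease Rnase1 was higher by 7.38 ± 1.51 and the elastase Cela3b, which did not pass, was at least 50.7-fold higher. The adipocyte and mesothelial list had a median of 1.45 (adjusted p = 2.30e-04; adjusted p = 0.462 with an estimated correlation). In it 3 of 14 rose and 11 did not pass in the fit of the 2 groups alone, with the basal keratin Krt14 at 7.65 ± 1.90 and the adipocyte hormone Adipoq, which did not pass, at 7.08 ± 2.25. None of its 14 genes passed adjusted over the list alone. Camera called upward the list of immediate early genes (median 0.34, adjusted p = 0.0124, and 0.697 as the adjusted p with an estimated correlation; 8 of 23 rose, 1 fell and 14 did not pass). It did the same for the list of epidermal growth factor, Notch, Hedgehog and Wnt signals (median 0.28, adjusted p = 0.0470, and 0.462 as the adjusted p with an estimated correlation; 9 of 26 rose and 17 did not pass). In the latter, the growth factor Areg was at least 114-fold higher and the receptor Erbb2 higher by 4.86 ± 1.61, and the median was -0.92 with normexp. Both calls were lost with the slide as a block, at medians of 0.25 and 0.34 (adjusted p = 0.0641 and 0.0528). In either list 0 genes passed adjusted over the list alone. Camera called 24 of the 40 lists in all. It did not call those of T cells (median -0.41), macrophages (-0.60), neutrophils (0.08), MHC class II (-0.08), chemokines (0.05), interferon-stimulated genes (-0.33), phase II conjugation (-0.81), transporters (-1.01), fatty acid synthesis (-0.46), endothelium (-0.24), endoplasmic reticulum stress (-0.72), the circadian clock (-0.13), red cells (-0.36), transforming growth factor beta (0.15), proinflammatory cytokines (0.25) and tumour-associated genes (-0.06). Adjusted over the list alone 3 chemokine genes rose (Ccl11, Ccl7 and Ccl21), as did 1 red cell gene. Of the clock genes Tef rose (1.68 ± 0.38) while Bmal1 and Npas2 fell (-1.31 ± 0.22 and -1.43 ± 0.33), and of the transforming growth factor list 2 rose and 1 fell. In the other 12 of these lists 0 genes passed adjusted over the list alone.

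By the rule for named genes, the next rises with a symbol were Rasl12 (at least 3.67-fold), Galnt16 (2.57 ± 0.24), Epdr1 (at least 3.57-fold) and Mustn1 (2.09 ± 0.22), none of which passed in the fit over all 6 arrays. Rasl12 and Epdr1 turned to -0.43 and -0.57 with normexp. The falls began with Ugt2b, a gene of glucuronidation, at -10.48 ± 1.04 (adjusted p = 0.201), followed by the clock gene Bmal1 (-1.31 ± 0.22), Tapbpl (-1.38 ± 0.26), Slc45a3 (-1.32 ± 0.26), the complement receptor C5ar2 (-1.27 ± 0.25), the Notch ligand Dll1 (-1.36 ± 0.27), the mitochondrial ribosomal protein Mrpl18 (-1.22 ± 0.24), Gadd45g (-1.40 ± 0.28) and Fam13a (-1.56 ± 0.32). The transcription factor Zkscan1 was not well above background at 2 weeks and was at least 2.79-fold lower there. These all passed in the fit of the 2 groups alone.

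**Figure D2:**
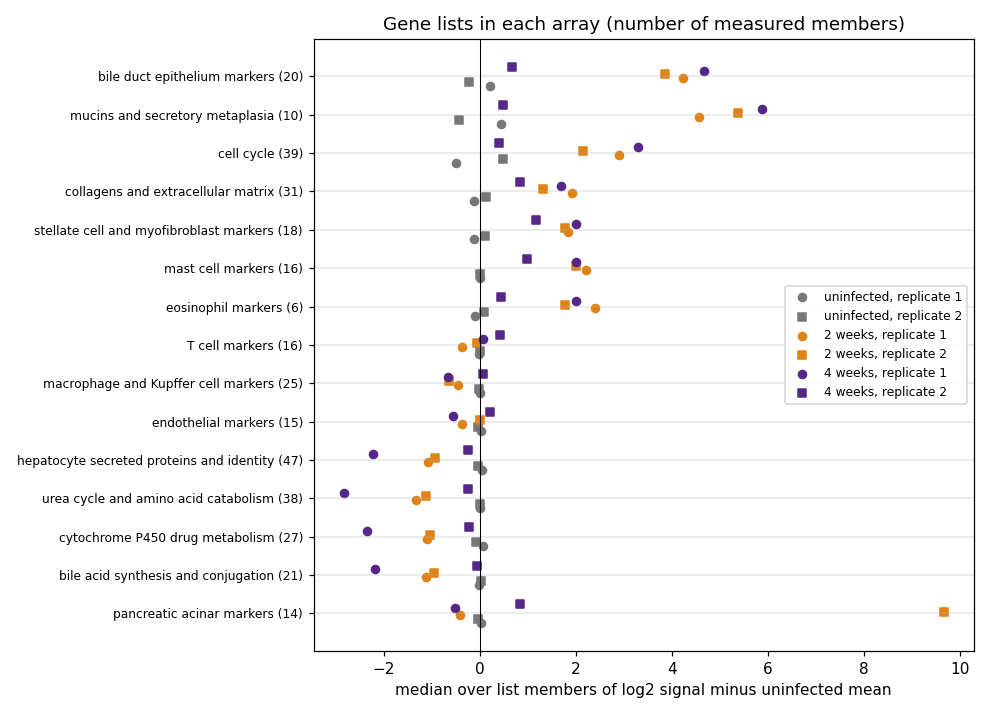
Median over the members of 15 gene lists of the log2 signal minus the uninfected mean, on the horizontal axis, for each of the 6 arrays; colours are groups and shapes are replicates. The bile duct list stands at 4.23 and 3.85 at 2 weeks but at 4.67 and 0.67 at 4 weeks. The pancreatic list stands at 9.66 in 1 array. With normexp the eosinophil median at 2 weeks turned to -0.48, where the median over all genes was -0.48 too.

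The comparison of 4 weeks with no infection asked which differences the liver held later in infection. At 4 weeks duct, matrix, myofibroblast and mast cell lists had higher medians and hepatocyte lists lower ones than in the uninfected liver, with no list called with an estimated correlation (smallest adjusted p = 0.570 with an estimated correlation). The 2 arrays differed: 4-week replicate 1 showed bile duct genes 4.67 above and hepatocyte genes at -2.23, whereas replicate 2 showed 0.67 and -0.25. Higher in both arrays than in either uninfected array, though short of the threshold, were Ccl11, at least 376-fold higher as a group (9.24 ± 0.42, n = 2, adjusted p = 0.0768, not passing), the smooth muscle actin Actg2 (3.50 ± 0.28, adjusted p = 0.257) and the phospholipase Pla2g2a (4.48 ± 0.52, adjusted p = 0.257). With the slide as a block these differences were 8.72, 3.64 and 4.72.

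In limma's fit over all 6 arrays 0 genes passed, with 2293 genes at an unadjusted p under 0.05 and 554 at least 2-fold apart at an unadjusted p under 0.01, 473 higher and 81 lower. Fitting the 2 groups alone, 0 genes passed too, with 1473 at an unadjusted p under 0.05. The median over all genes was -0.05, or -0.15 without 4-week replicate 2 and 0.04 without 4-week replicate 1. A fit without either array keeps 1 array at 4 weeks and so holds none of the spread of that group. The groups did not overlap for 54.6% of genes, where chance gives 33.3%. Of the genes 2-fold apart, 85.4% were higher in the main scaling, 45.0% after quantile normalization and 52.1% with median centring.

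Matrix and myofibroblast genes were higher in both 4-week arrays. The extracellular matrix list had a median of 1.40 (1.68 in replicate 1 and 0.84 in replicate 2; 1.04 with the slide as a block), and adjusted over the list alone 14 of 31 genes rose, against 0 over all genes. The stellate cell and myofibroblast list had a median of 1.43 (2.01 and 1.18; 1.63 with the slide as a block), with 8 of 18 genes rising adjusted over the list alone. Mfap5 was higher by 2.80 ± 0.33, Lum by 3.17 ± 0.58, Dcn by 2.43 ± 0.45, Tpm2 by 2.38 ± 0.35 and Des by 2.97 ± 0.49. Postn and Cnn1 were higher at least 17.7-fold and 3.72-fold, though Cnn1 turned to -0.53 with normexp. The progenitor list had a median of 1.67 (2.08 in replicate 1 and 0.97 in replicate 2), with 4 of 14 genes rising adjusted over the list alone. The protease list had a median of 1.68 (2.40 and 0.69), with 0 of 20. Camera called these 4 lists upward (adjusted p = 2.68e-08, 5.51e-06, 1.75e-04 and 3.47e-04). None was called with an estimated correlation (adjusted p = 0.570 with an estimated correlation for each).

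Duct, mucin and cell cycle genes were high in replicate 1. The bile duct list had a median of 2.59 (2.31 with the slide as a block), with 1 of 20 genes rising adjusted over the list alone, and Krt7 (6.42 ± 2.34) and Cldn4 (5.98 ± 2.31) did not pass. The mucin list had a median of 2.87 (5.87 and 0.47 in the 2 arrays), with 1 of 10 genes rising adjusted over the list alone, and Tff1 was at least 330-fold higher. The cell cycle list had a median of 2.04 (3.30 and 0.40), with 0 of 39 genes passing adjusted over the list alone. Camera called the 3 lists upward (adjusted p = 6.95e-05, 0.00596 and 6.67e-08). None was called with an estimated correlation (adjusted p = 0.570, 0.570 and 0.607 with an estimated correlation).

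Among immune genes, the mast cell list had a median of 1.54 (2.01 in replicate 1 and 0.99 in replicate 2), with 5 of 16 genes rising adjusted over the list alone, Fcer1a at 1.98 ± 0.44 and Tph1 at least 1.75-fold higher. The eosinophil list had a median of 1.29 (2.00 and 0.43), or 0.38 with members at their bound, and Rnase2 was at least 3.32-fold higher; 1 of 6 genes rose adjusted over the list alone. The chemokine list had a median of 0.52, with 6 of 29 genes rising adjusted over the list alone, among them the lymphoid chemokine Ccl21 (2.70 ± 0.34) and, at least 6.64-fold, the monocyte chemoattractant Ccl7. The type 2, B cell, MHC class II and proinflammatory lists had medians of 0.68, 0.59, 0.49 and 0.47, with 1, 0, 0 and 0 genes rising adjusted over the list alone. Mzb1 was higher by 2.47 ± 0.53, Batf3 by 1.47 ± 0.46 and Irf8 at least 1.74-fold. Camera called these 7 lists upward (adjusted p = 3.99e-05, 0.0121, 0.0122, 0.0121, 0.0416, 0.0215 and 0.0215). None was called with an estimated correlation (adjusted p = 0.570 with an estimated correlation for each). With normexp the medians of the mast cell, eosinophil, type 2, B cell, MHC class II and proinflammatory lists turned to -0.21, -0.68, -0.62, -0.67, -0.21 and -0.09, with these 6 calls lost. Genes that turned with it were Fcer1a (-0.18), Tph1 (-1.05), Rnase2 (-0.46), Batf3 (-0.21) and Irf8 (-1.13). The median over all genes was -0.44 with normexp, so such values are relative to that shift. The type 2, MHC class II and proinflammatory calls were lost with the slide as a block, at medians of 0.41, 0.05 and 0.54 (adjusted p = 0.0905, 0.998 and 0.0944).

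Lists of hepatocyte genes had lower medians, mostly through replicate 1. The medians were -1.23 for the hepatocyte list, -1.50 for the urea cycle and amino acid list, -1.11 for fatty acid oxidation, -1.34 for cytochrome P450, -1.24 for bile acid synthesis, -1.27 for transporters and -1.0 for fatty acid synthesis, and 0 genes of these lists passed adjusted over the list alone. With the slide as a block they were -0.91, -1.24, -0.93, -1.37, -1.03, -1.20 and -0.52, and the call of fatty acid synthesis was lost (adjusted p = 0.137). Examples were F7 (-2.20 ± 0.66), Tdo2 (-1.78 ± 0.58), the fatty acid oxidation genes Crot (-1.99 ± 0.61) and Hadha (-1.57 ± 0.47), Cyp2b1 (-3.22 ± 0.84) and the efflux transporter Abcg2 (-2.20 ± 0.48). In replicate 2 the 7 list medians ran from -0.45 for fatty acid oxidation to 0.17 for fatty acid synthesis, with transporters at -0.09. In replicate 1 the medians of these 3 were -1.85, -2.36 and -2.45. Camera called the 7 lists downward (adjusted p = 2.68e-08, 2.61e-07, 5.32e-07, 0.00106, 0.00596, 0.0318 and 0.00658). None was called with an estimated correlation (adjusted p = 0.601, 0.618, 0.570, 0.636, 0.636, 0.570 and 0.636 with an estimated correlation). The acute phase, sex-dependent and endoplasmic reticulum stress lists were called downward too, with medians of -0.92, -1.37 and -0.44 (adjusted p = 0.0128, 0.0121 and 0.0416, and adjusted p = 0.636, 0.636 and 0.570 with an estimated correlation). In replicate 1 their medians were -1.65, -2.16 and -0.88, against -0.11, -0.31 and -0.19 in replicate 2. The adipocyte and mesothelial list (median 1.87, adjusted p = 3.47e-04) and the immediate early list (median 0.49, adjusted p = 0.0299) were called upward (adjusted p = 0.570 and 0.636 with an estimated correlation). The adipocyte median was 3.03 in replicate 1 and 0.96 in replicate 2. Without 4-week replicate 1 the immediate early median was 0.05 and camera's direction turned. The calls of endoplasmic reticulum stress, adipocyte and immediate early genes were lost with the slide as a block, at medians of -0.42, 0.86 and 0.44 (adjusted p = 0.0905, 0.0905 and 0.491). The pancreatic list, at a median of -0.03 (-0.51 and 0.84 in the 2 arrays), was not called. With the slide as a block its median was 9.75, which comes from 2-week replicate 2. In these last 6 lists 0 genes passed adjusted over the list alone. With normexp, camera read the acute phase, fatty acid synthesis and endoplasmic reticulum stress lists upward against the other genes, at medians of -0.01, -0.25 and -0.08, and none of the 10 lists named as downward was called downward. Camera called 26 lists in all. It did not call those of T cells (median 0.31), natural killer cells (-0.26), macrophages (-0.35), neutrophils (0.47), interferon-stimulated genes (-0.32; -0.87 and 0.55 in the 2 arrays), phase II conjugation (-0.58), cholesterol synthesis (-0.45), endothelium (-0.06), the circadian clock (-0.33), red cells (-0.47), growth factor, Notch, Hedgehog and Wnt signals (0.38), transforming growth factor beta (0.33) and tumour-associated genes (0.16). Adjusted over the list alone 1 phase II gene (Ugt2b1), 1 clock gene (Bmal1) and 1 gene of the transforming growth factor list (Inhba) fell, 1 red cell gene and 1 gene of the transforming growth factor list rose, and 0 passed in the other 9 of these lists.

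Other genes named by the rule, none passing, were Galnt16 (2.38 ± 0.24), Gpm6b (1.86 ± 0.21), Sctr, Rasl12, Shd and Ltb4r, the last 4 at least 2.63-fold, 2.68-fold, 2.74-fold and 2.14-fold higher, and Reg3g, at least 2.6-fold higher. With normexp Gpm6b, Sctr, Rasl12, Shd, Ltb4r and Reg3g turned to -0.32, -0.76, -0.67, -0.90, -0.85 and -0.70. On the low side were Ugt2b1 (-3.25 ± 0.47), Mettl7b (-3.49 ± 0.59), the steroid carrier Shbg (-1.80 ± 0.29), the choline kinase Chka (-2.06 ± 0.40), the activin subunit Inhba (-1.74 ± 0.34), Fam13a (-1.68 ± 0.32), Lce1e (-1.48 ± 0.25), Rbmx (-1.44 ± 0.28), Tecpr1 (-1.40 ± 0.21) and Bmal1 (-1.23 ± 0.22).

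**Figure D3:**
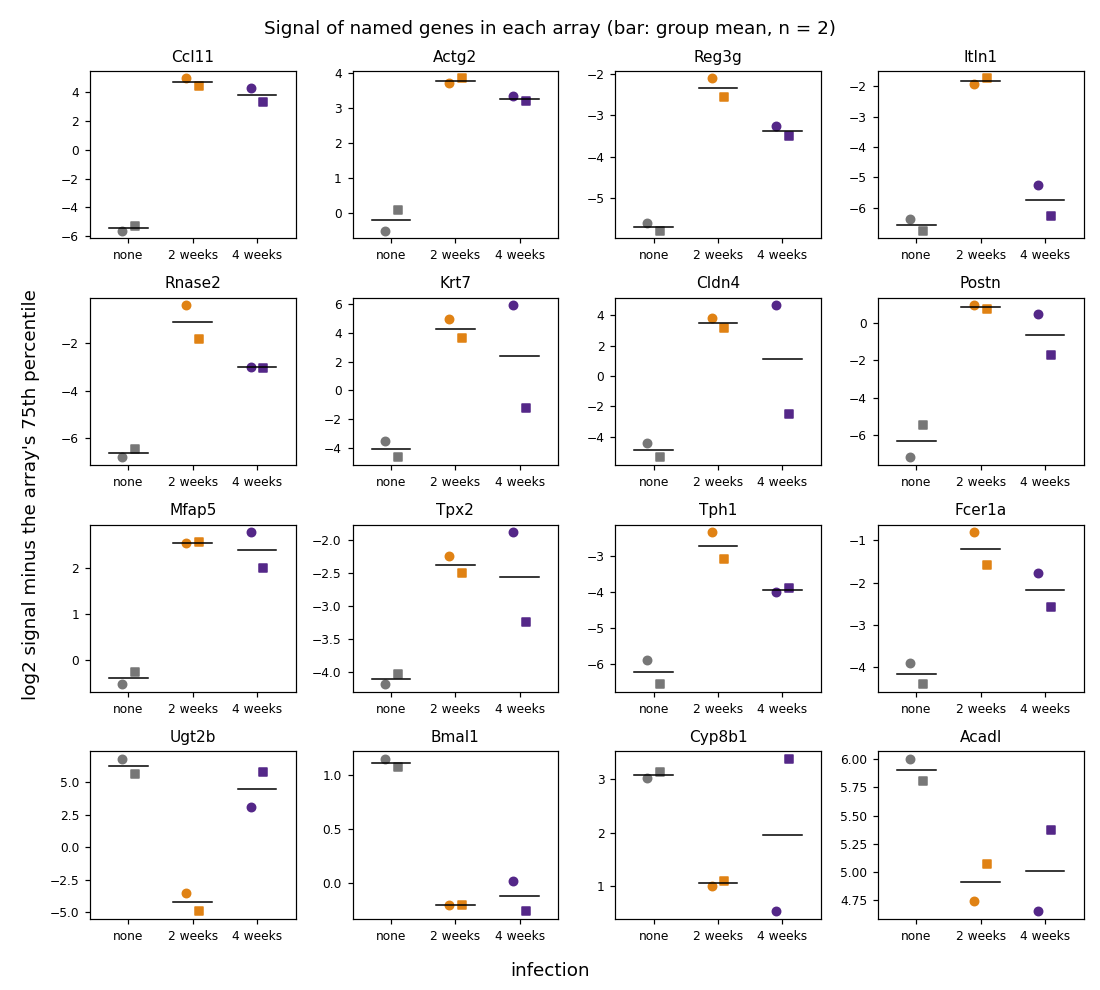
Log2 signal minus the array's 75th percentile for 16 named genes, by infection group; points are arrays (circle, replicate 1; square, replicate 2) and bars are group means of 2 arrays, with no error bars. Ccl11 and Actg2 lie above the uninfected arrays in all 4 infected arrays, and Krt7 and Cldn4 differ widely between the 4-week arrays. With normexp the difference of Tpx2 at 2 weeks turned to -0.59, where the median over all genes was -0.48.

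Differences at 2 and 4 weeks ran in the same direction for 86.4% of genes, and the log2 differences correlated with r = 0.917 across genes. Both comparisons share the uninfected arrays; with no effect at all, simulated groups against them gave r = 0.503. The covariance was 1.23, against 0.159 in simulation. Since 0 genes were called at 4 weeks in limma's fit over all 6 arrays, the overlap of called genes could only be 0. The 0 expected from independent lists was fixed in the same way. Setting these beside the 0 in simulation therefore shows nothing. At least 2-fold apart at an unadjusted p under 0.01 in both and in the same direction were 330 genes, 306 higher and 24 lower, against 12.1 and 0.194 from independent lists and a mean of 43.4 over 100 simulations, with a highest of 62. The 2 controls were not split between the comparisons. The simulation holds the shared controls but draws each gene on its own, with the same spread in all 3 groups and no slide effect. Genes that move together would widen its range, so its highest of 62 sets no firm limit. Both uninfected arrays lay on slide 2, and 2-week replicate 1 and both 4-week arrays on slide 1. Part of the excess may thus come from sources other than infection.

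The comparison of 4 with 2 weeks asked what differed between the stages of infection. Among the genes with lower means at 4 weeks were the lectin Itln1, which was not well above background at 4 weeks (at least 5.98-fold lower; log2 difference -3.93 ± 0.40, adjusted p = 1.00), Retnlb (-4.13 ± 1.20), Mptx1 (-4.54 ± 0.90) and the ribonucleases Rnase2 (-1.90 ± 0.50) and Rnase3 (at least 2.66-fold lower). With a higher mean at 4 weeks stood Ugt2b (8.72 ± 1.04), at the level of 3.13 and 5.81 in the 4-week arrays against -3.57 and -4.94 at 2 weeks. None of these passed; with the slide as a block the differences were -3.85 for Itln1, -4.63 for Retnlb, -4.49 for Mptx1 and 8.03 for Ugt2b.

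In limma's fit over all 6 arrays 0 genes passed, with 260 at an unadjusted p under 0.05 and 37 at least 2-fold apart at an unadjusted p under 0.01, 20 higher and 17 lower. The fit of the 2 groups alone called 0 genes, with 142 at an unadjusted p under 0.05. The median over all genes was 0.04, or 0.20 without 4-week replicate 1 and -0.01 without 4-week replicate 2. Either of the latter fits keeps 1 array at 4 weeks and so holds none of the spread of that group. The groups did not overlap for 18.4% of genes, below the 33.3% that chance gives.

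Camera called 16 lists, 3 upward and 13 downward, and none with an estimated correlation, where the smallest adjusted p was 0.698. Upward were T cell markers (median 0.46, adjusted p = 1.78e-05, and adjusted p = 0.698 with an estimated correlation), MHC class II genes (0.50, adjusted p = 2.95e-04, and adjusted p = 0.856 with an estimated correlation) and natural killer cell genes (0.28, adjusted p = 0.0476, and adjusted p = 0.903 with an estimated correlation). The natural killer median turned to -0.08 without 4-week replicate 2. With the slide as a block the medians of these 3 upward lists were 0.51, 0.23 and 0.41, and the call of MHC class II was lost (adjusted p = 0.123). Examples were Cd27 (0.79 ± 0.23), Cd8a (0.78 ± 0.33), the class II genes RT1-Da (0.65 ± 0.33) and Cd74 (0.55 ± 0.30), their regulator Ciita (0.54 ± 0.25), and, of the chemokine list, which was not called, the B cell chemoattractant Cxcl13 (1.90 ± 0.47). Downward were the mucin list (-2.11, adjusted p = 1.26e-07, and adjusted p = 0.856 with an estimated correlation), the bile duct list (-1.47, adjusted p = 3.96e-04, and adjusted p = 0.903 with an estimated correlation), the mast cell list (-0.75, adjusted p = 1.26e-07, and adjusted p = 0.856 with an estimated correlation) and the cell cycle list (-0.56, adjusted p = 7.73e-06, and adjusted p = 0.903 with an estimated correlation). The mucin, duct and cell cycle lists rest on 4-week replicate 2: without it their medians were 0.49, 0.81 and 0.63, and that of the mast cell list was -0.22 with its call lost (adjusted p = 0.564). The mucin median was 5.87 in 4-week replicate 1 and 0.47 in replicate 2, against 4.56 and 5.39 at 2 weeks. The pancreatic list (-4.33, adjusted p = 7.01e-09, and adjusted p = 0.861 with an estimated correlation) rests on 2-week replicate 2. Its median was 0.13 and its call was lost (adjusted p = 0.939) with the slide as a block, which leaves that array out of the comparison. The eosinophil list was called downward (-0.81, or -0.07 without 4-week replicate 2, adjusted p = 0.0402, and adjusted p = 0.856 with an estimated correlation), as were those of the extracellular matrix (-0.17, adjusted p = 0.0395; 0.26 without 4-week replicate 2 and 0.05 without 2-week replicate 1) and of stellate cells and myofibroblasts (-0.23, adjusted p = 0.0191; -0.02 without 4-week replicate 2), with adjusted p = 0.903 and 0.861 with an estimated correlation. The stellate call was lost with the slide as a block, at a median of -0.15 (adjusted p = 0.107). Hepatocyte lists called downward were those of transporters (-0.24, adjusted p = 0.0395), fatty acid synthesis (-0.39, adjusted p = 0.00416), fatty acid oxidation (-0.18, adjusted p = 0.00878), the urea cycle (-0.27, adjusted p = 0.0188) and hepatocyte identity (-0.23, adjusted p = 0.00750). For these 5 the adjusted p = 0.903, 0.903, 0.903, 0.932 and 0.932 with an estimated correlation, and without 4-week replicate 1 their medians were 0.63, 0.51, 0.49, 1.01 and 0.72. All 5 calls were lost with the slide as a block, at medians of -0.15, -0.28, -0.09, -0.16 and -0.11 (adjusted p = 0.0536, 0.123, 0.0758, 0.123 and 0.107). Adjusted over the list alone 1 mucin gene, Itln1, fell, and 0 genes of the other 39 lists passed; over all genes 0 passed. Named members of these lists were Krt19 (-2.42 ± 2.21), Cd24 (-1.65 ± 1.40), Tff1 (-3.15 ± 2.25), Tff2 (-2.87 ± 2.30, and 0.07 with the slide as a block), Tph1 (-1.23 ± 0.38), Mcpt8 (-0.84 ± 0.35), Rnase1 (-4.06 ± 1.51) and Cela3b (-4.57 ± 2.44), none passing. Without 4-week replicate 2, Krt19, Cd24 and Tff1 turned to 0.99, 0.51 and 0.32.

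Of the other genes named by the rule, none passing, Rhcg and Pfn4 were not well above background at 2 weeks and were at least 2.99-fold and 2.27-fold higher at 4 weeks. Prp2 (1.47 ± 0.26), the serine protease Prss34 (1.52 ± 0.27), Or52s1b (1.23 ± 0.22), Fgf11 (1.33 ± 0.30), Irx6 (1.38 ± 0.31), the hyaluronan receptor Hmmr (2.44 ± 0.57) and Cdh23 (1.02 ± 0.24) had higher means at 4 weeks. Reg3g (-1.06 ± 0.26), Csta (-1.33 ± 0.41), Rnase1l2 (-3.80 ± 1.21) and the hepatokine Fgf21 (-1.45 ± 0.48) had lower means.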

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

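The tests of 4-week replicate 2, of a response of pancreatic genes to infection and of the share of hepatocytes were chosen only after the results they weigh were seen; the comparison of lists and the test on islet genes were set before. The test on exocrine genes was set before its own values were seen, but was devised in response to the result of the islet test.

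What drew attention was a difference between the effects at 4 and 2 weeks, tested with camera at the preset correlation. The medians of 4 minus 2 weeks were -1.47 for bile duct markers, -2.11 for mucins, -0.17 for the extracellular matrix, -0.23 for stellate cells and myofibroblasts, -0.56 for the cell cycle, -0.81 for eosinophils, -0.75 for mast cells, 0.46 for T cells, 0.28 for natural killer cells and 0.50 for MHC class II. They were -0.24 for transporters, -0.39 for fatty acid synthesis, -0.18 for fatty acid oxidation, -0.27 for the urea cycle, -0.23 for hepatocyte identity and -4.33 for pancreatic acinar genes. With an estimated correlation between genes none of these 16 differences passed (smallest adjusted p = 0.698). The bile duct, extracellular matrix, cell cycle and natural killer differences turn without 4-week replicate 2, where the mucin median turns to 0.49 and the stellate cell, eosinophil and mast cell medians are nearer 0 at -0.02, -0.07 and -0.22. The extracellular matrix median turns without 2-week replicate 1 too, to 0.05. Those of transporters, fatty acid synthesis, fatty acid oxidation, the urea cycle and hepatocyte identity turn without 4-week replicate 1, and the pancreatic one rests on 2-week replicate 2.

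In 4-week replicate 2 the bile duct list stood 0.67 above the uninfected mean, against 4.67 in replicate 1. An exchange with an uninfected array would leave an uninfected array with raised duct genes, but the bile duct list differed by only 0.43 between the uninfected arrays. For a wrong label on uninfected liver, the extracellular matrix list stood 0.84 above the uninfected mean, against 0.26 between the uninfected arrays. Those 2 arrays share slide 2, while 4-week replicate 2 lay on slide 1, so the 0.26 holds no difference between slides. In the 2-week arrays, on slides 1 and 2, the list stood at 1.92 and 1.31. A slide difference could thus make up part of the 0.84, and the test does not exclude a wrong label. An effect shared by the arrays of a slide could not part the 4-week arrays, since both lay on slide 1. The 2-week arrays, on different slides, differed by a median of only 0.38 over the bile duct list (quartiles 0.19 and 0.69), and the 4-week arrays, on 1 slide, by 4.48 (1.29 and 5.56). An effect on a single array was not tested. The same affected tissue in a smaller share would give alike shares of the rise of replicate 1 on the linear scale, but over the members at least 2-fold above the uninfected mean in replicate 1 the median share was 58.5% for 14 of 18 stellate and myofibroblast genes (quartiles 17.2% and 114%) and 1.02% for 16 of 20 bile duct genes (0.616% and 1.90%). A different piece of liver with few large ducts, or an animal with a milder infection, stays open and was not tested.

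In 2-week replicate 2 the pancreatic list stood 9.66 above the uninfected mean, with the trypsinogen Prss1 at 13.09, or 12.04 with dim signals raised to the lowest signal well above background of their array. A response to infection of like size in the list as a whole is argued against, as the median was -0.42 in 2-week replicate 1 (quartiles -1.12 and 1.20), against quartiles of 7.11 and 10.74 in replicate 2. With dim signals so raised, the upper quartile in replicate 1 was 0.59 and the lower one in replicate 2 still 7.11. For Rnase1 and Cela1, at 5.35 and 1.40 in replicate 1, a response cannot be told apart from other causes, since only these 2 members were raised there and well above background at 4 weeks too. The median over them of the lower 4-week array was 1.63. This test was first run without that floor and on more members, and was narrowed after its value was seen. Both genes were higher in replicate 2, at 9.41 and 8.96. For pancreatic tissue with its islets, 5 islet genes of 10 were measured. Over them the median of 2-week replicate 2 minus the highest other array was -0.75, and 0 of the 5 were highest in it. A gene well above background in this array alone would have been left out by the filter on dim probes. The test therefore speaks only for these 5 genes and cannot exclude islets. Exocrine pancreatic tissue goes with the values. Over 6 exocrine genes outside the list the median was 3.18 over the highest other array, where 3 had been set. That is only just above, with Pla2g1b at 8.61 and Bhlha15 at 0.10. Carried-over exocrine tissue or enzyme-producing cells within the liver could each give this, and they were not told apart.

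Hepatocyte genes were low in both 2-week arrays and in 4-week replicate 1, where duct and stromal genes were high. In 4-week replicate 2 the stellate cell and myofibroblast list stood at 1.18 and the hepatocyte list at only -0.25. A lower share of hepatocytes would raise the markers of every other cell type alike, but at 2 weeks the lower quartile of the bile duct list was 1.68, against upper quartiles of -0.04 for macrophages and 0.46 for endothelium, so it is argued against for the raised lists. For the hepatocyte genes themselves it cannot be told apart from lower expression per cell. In 4-week replicate 1 the median of the urea cycle list was -2.83, just outside the quartiles of the hepatocyte list, -2.64 and -1.74, while the ranges between the quartiles of both lists overlap. The bound for this test was first set at those quartiles, which the median crosses, and was changed to the overlap of the ranges after the value was seen, so the test decides little.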

How the results depend on the processing

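The normexp setting was chosen only after the data were seen, in place of one planned on mean spot signals, which was not run; the other settings were planned. Where an array was left out and its group kept 1, that array is assumed to vary like the other groups. Signal over background limits dim genes, and 2 arrays per group limit all results.

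Of 382, 414 and 254 values of called lists under other scalings, filters, probe rules, fits and blocks, for 2 weeks, 4 weeks and 4 against 2 weeks, 343, 367 and 226 kept their direction and their side of the threshold, 31, 41 and 28 lost the call and 8, 6 and 0 turned. With each array left out, of 144, 156 and 96 such values 129, 132 and 66 were the same, 15, 23 and 19 lost the call and 0, 1 and 11 turned. All list calls were lost with an estimated correlation and with fry, which these counts leave out. Of 998, 688 and 509 values of named genes under the former settings, 859, 676 and 508 were the same, 7, 0 and 0 lost the call, 121, 0 and 0 gained it and 11, 12 and 1 turned. With each array left out, of 384, 264 and 198 values 260, 221 and 186 were the same, 4, 0 and 0 lost the call, 120, 43 and 8 gained it and 0, 0 and 4 turned. The cause was not tested unless stated. With every probe on its own, lists and named genes were still taken by the main rule for probes, so these values equal the main ones. The fits of the 2 groups alone, the intensity trend, the array weights and the replicate block leave every log2 difference as it was. Leaving out an array of a group outside the comparison does the same. The values counted as the same thus include many that could not turn.

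The single call at 2 weeks, Ccl11, is lost (0 genes called) with normexp, quantile normalization, median centring and the percentile over probes above background on all arrays. It is lost too with every probe on its own, the authors' values, the slide as a block, and at an adjusted p under 0.01. With the filter on all 6 arrays Ccl11 was not tested, and 0 genes were called. In the fit of the 2 groups alone 4160 genes were called and with array weights 4844, since the 4-week arrays, with weights of 0.230, then add little or no spread. With the replicate number as a block 0 genes were called at 2 weeks. The labels do not say whether the numbers pair the samples. The differences between replicates correlated at -0.01, 0.03 and 0.32 between groups, the last between 2 and 4 weeks.

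Genes 2-fold apart at an unadjusted p under 0.01 (527, 554 and 37 for 2 weeks, 4 weeks and 4 against 2 weeks) numbered 57, 17 and 3 with normexp, 238, 227 and 12 with the filter on all 6 arrays, where fewer genes were tested, 2983, 330 and 21 in the fits of 2 groups alone, 2977, 227 and 11 with array weights, and 164, 58 and 19 with the slide as a block. They numbered 324 at 2 weeks with quantile normalization, 368 at 4 weeks with the floor, and for 4 against 2 weeks 130 with no filter and 17 with the intensity trend and robust prior. Lists called numbered 13 at 4 weeks with normexp and 8 for 4 against 2 weeks with the slide as a block. With an estimated correlation and with fry, 0 lists were called in each comparison, against 24, 26 and 16.

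Normexp left an offset before scaling, which compresses dim signals, and the all-gene median moved to -0.48 and -0.44 at 2 and 4 weeks. At 2 weeks, list medians under it were -0.48 for eosinophils, -0.71 for B cells, -0.71 for type 2 (call lost, adjusted p = 0.853), 0.083 for mast cells, 0.117 for progenitors, 0.08 for the acute phase, 0.16 for cholesterol, -0.10 for fatty acid oxidation, -0.29 for the urea cycle, -0.14 for hepatocytes and -0.92 for growth factor and Notch signals. At 4 weeks they were -0.68 for eosinophils, -0.67 for B cells, -0.62 for type 2, -0.21 for mast cells, -0.21 for MHC class II, -0.09 for proinflammatory genes, -0.007 for the acute phase, -0.25 for fatty acid synthesis and -0.08 for endoplasmic reticulum stress; the last 3, and fatty acid oxidation, urea cycle and hepatocytes at 2 weeks, turned against the other genes. Genes that turned at 2 weeks were Rasl12 (-0.43), Reg3g (-0.062), Epdr1 (-0.57), Sctr (-1.10), Cnn1 (-0.45), Tpx2 (-0.59), Cenpf (-0.26), Il1rl1 (-0.71), Rnase3 (-0.42), Ccr3 (-0.35) and Tph1 (-0.32). At 4 weeks they were Rasl12 (-0.67), Sctr (-0.76), Gpm6b (-0.32), Reg3g (-0.70), Shd (-0.90), Ltb4r (-0.85), Cnn1 (-0.53), Rnase2 (-0.46), Tph1 (-1.05), Fcer1a (-0.18), Batf3 (-0.21) and Irf8 (-1.13). With the slide as a block the MHC class II median at 4 weeks was 0.049, with camera's direction turned but at an adjusted p of 0.998, and Tff2 for 4 against 2 weeks was 0.071.

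With each array left out, genes called ran from 0 to 4160 at 2 weeks, from 0 to 7283 at 4 weeks and from 0 to 768 for 4 against 2 weeks, and genes called in both infected groups from 0 to 3978. Genes 2-fold apart ran from 156 to 2983, 120 to 5378 and 19 to 1915, and lists called from 13 to 26 at 4 weeks and 8 to 24 for 4 against 2 weeks. The immediate early median at 4 weeks ran from 0.046 to 0.859, with camera's direction turned at 0.046. For 4 against 2 weeks the medians ran from -3.78 to 0.81 for bile duct, -0.52 to 0.26 for extracellular matrix, -0.417 to -0.019 for stellate cells, -1.98 to 0.63 for the cell cycle, -0.084 to 0.615 for natural killer cells, -1.17 to 0.63 for transporters, -1.52 to 0.51 for fatty acid synthesis, -0.84 to 0.49 for fatty acid oxidation, -1.59 to 1.01 for the urea cycle and -1.16 to 0.72 for hepatocytes. Tff1 ran from -6.63 to 0.32, Tff2 from -5.82 to 0.071, Krt19 from -5.82 to 0.99 and Cd24 from -3.81 to 0.51.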

Other observations

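The genes of this part were chosen after their values were seen.

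The probe for Ugt2b, a gene of glucuronidation, read 6.79 and 5.67 without infection, -3.57 and -4.94 at 2 weeks, and 3.13 and 5.81 at 4 weeks, on the log2 scale relative to the 75th percentile of each array. Its neighbour in name, Ugt2b1, was lower at 4 weeks by a log2 difference of -3.25 ± 0.47 (limma, adjusted p = 0.257).

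Itln1, Mptx1 and Retnlb were above both uninfected arrays at 2 weeks and lower at 4 weeks, where Mptx1 lay below both uninfected arrays. Itln1 read -1.91 and -1.73 at 2 weeks and was not well above background in the other 4 arrays, where the lowest signals well above background lay between -4.94 and -4.11. Mptx1 read -2.98 and -2.71 without infection, -0.36 and -0.25 at 2 weeks and -3.47 in 4-week replicate 1, and was not well above background in replicate 2. Retnlb read 1.15 and 0.14 at 2 weeks and -1.77 in 4-week replicate 1, and was not well above background in the uninfected arrays or in 4-week replicate 2.

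Among clock genes, Bmal1 read 1.14 and 1.07 without infection and -0.20 and -0.20 at 2 weeks, and Tef -1.97 and -1.53, then -0.08 and -0.07. The labels used here give no hour of sampling. Interferon-stimulated genes had a median of -0.87 in 4-week replicate 1 and 0.55 in replicate 2, relative to the uninfected mean.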
